A study of Mus musculus with 6 samples.

How the data were processed

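RNA was measured in 6 samples of Gli1-lineage cells sorted from adult mouse ovaries, 3 labelled in the fetus and 3 labelled after birth, on 1-colour oligonucleotide arrays. Per the labels' protocols, a fixed volume of total RNA was amplified from every sample because concentrations varied, so the mass of RNA entering the amplification differed between samples by an amount not given in the sources used here. The values the authors deposited are linear probe set intensities, and the submitters' processing notes name MAS5, a method that computes 1 background-corrected signal per probe set from its perfect-match and mismatch probes; its version and settings are not given in the sources used here. On every deposited array the mean intensity after trimming 2% at each end was 500, so the arrays had been scaled to a common level before deposit, and no further normalization was applied for the main results.

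The table held 45101 probe sets. The 64 control probe sets were left out of every test and examined separately. Of the remaining 45037, 34945 had 1 gene symbol in the platform annotation used here, 932 had several and 9160 were unnamed here. Probe sets with several symbols named no gene. For 34741 of the named probe sets the gene identifier matched a mouse RefSeq gene table (assembly GRCm38.p6), which changed 0 symbols and was used for names only; no genome positions are given, because the sources used here name no build for the array.

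Intensities were moved to the scale log2(signal + 16). A fold change on this scale understates the change of dim genes. Each of 18193 genes was represented by the probe set with the highest mean over all 6 arrays, and genes whose probe set lay below the 40th percentile of all probe sets (a signal of 99.4) were not tested, which left 11703. No detection calls were used; that level served as the floor. Where all 3 arrays of a group lay below it, the fold is given as a bound, the brighter group's mean against the floor or the dim probe set's own signal if higher. A gene's other probe sets past the floor were compared with the one reported. Of the 99 genes picked by the naming rule, 51 had such probe sets, and for 13 of these at least 1 went the opposite way.

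The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with the group as the only factor and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05. Changes are mesonephros-derived minus ovary-derived, with standard errors (SE) from the same fit. Of the 22 gene lists, fixed before the data were examined, 18 had at least 3 tested members and were compared with all other genes by camera in limma with a preset correlation of 0.01 between genes, adjusted over the 18 lists. Camera with an estimated correlation, and fry, which tests whether a list's genes move one way without reference to other genes, were run beside it. The number of members past the threshold was also counted with p-values adjusted over the list alone. The lists covered androgen synthesis, cholesterol synthesis and uptake, the hedgehog pathway, gonadal and mesonephric transcription factors, theca growth factors and receptors, fibroblast and extracellular matrix genes, the cell cycle, the dissociation and immediate early response, the interferon response, oxidative phosphorylation, cytosolic ribosomal proteins, and markers of granulosa, luteal, oocyte, endothelial, smooth muscle and pericyte, macrophage, lymphoid, erythroid, ovarian surface epithelial, tubule epithelial and adipocyte identity.

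Genes were named by a rule fixed before the data were examined. It took, in each direction, the 10 genes with the largest change among those past the threshold whose groups did not overlap, filled with the smallest unadjusted p among non-overlapping genes where fewer passed; then up to 4 members with the smallest p in each list described; and always a fixed set of ovarian, hedgehog and steroidogenic genes. Where a list is described with fewer examples, the remaining members picked by the rule are covered by its counts.

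The number of arrays, 3 per group, limits the precision. No 2 arrays held identical values. The labels number the samples in each group but do not say whether they came from separate animals, so p-values measure the spread between these samples, which may be technical.

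Alternatives fixed before the data were examined were pseudocounts of 1 and 64, no floor or a floor at the 60th percentile, quantile normalization, median centring, the mean of a gene's probe sets, all probe sets, leaving out probe sets with _x_at or _s_at names, eBayes without the trend or with robust fitting, array weights, a plain test with equal variances, the replicate number as a block, and leaving out each array. Settings that change the values or leave out arrays or probe sets choose the probe set of each gene and the floor anew, and values of single genes without 1 array are given in the report on the main probe set. Added after the control probe sets had been seen were a comparison of mesonephros-derived replicate 3 alone with the 3 ovary-derived arrays, and a fit with the poly-A spike signal as a covariate. The gene test was tested on simulated data with the means, gene variances and unequal array noise of these 11703 genes, of which 200 were changed, in 20 runs. It recovered 12.4% of the 2-fold and 62.6% of the 4-fold changes, with 3.3 wrong calls per run on average. In 100 simulated runs, camera found a list of 20 genes shifted by 1 log2 unit in 100 and called 0.04 unchanged lists per run, with noise independent between genes. The estimated correlation between genes of a real list reached 0.798 (macrophage markers), so that rate does not carry over to lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.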

Results

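Gli1 is a transcription factor that is switched on by hedgehog signalling and marks precursors of theca cells, the steroid-producing and contractile cells that wrap ovarian follicles. In mice carrying a tamoxifen-inducible Cre under Gli1 control and a Cre-activated tdTomato reporter, cells that expressed Gli1 at the time of tamoxifen keep a red label for life. Cells of mesonephric origin were labelled at E12.5, again at E14.5 and last at E16.5, and cells arising within the ovary were labelled on postnatal days 1 to 3 through the nursing dam. Labelled cells were sorted from ovaries at 2 months of age, and their RNA was measured on 3 arrays per group. The comparison asks how the cells of these 2 origins, as the labels name them, differ in the adult ovary. Origin and the time of tamoxifen changed together between the groups, so their effects cannot be told apart here. Over all 45037 probe sets without controls, arrays of ovary-derived cells correlated with each other at 0.963 to 0.973. Arrays of mesonephros-derived cells correlated at 0.845 to 0.896, and arrays of different groups at 0.871 to 0.950. Mesonephros-derived replicate 3 correlated at 0.946 to 0.950 with the ovary-derived arrays and at 0.876 and 0.896 with replicates 1 and 2 of its own group, so it lay closer to the other group than to its own. This was not particular to replicate 3. Replicates 1 and 2 correlated with each other at 0.845, below their values with the ovary-derived arrays, 0.871 to 0.875 for replicate 1 and 0.887 to 0.893 for replicate 2.

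The spike-in transcripts, which in the standard protocol of these arrays are added in equal amounts, read unequally. Poly-A spikes, which go in before amplification, stood at 15.3, 14.46 and 2.46 times the ovary-derived mean in mesonephros-derived replicates 1, 2 and 3, against 0.677, 0.830 and 1.78 times in the ovary-derived replicates. Spikes added at hybridisation stood at 3.42, 2.77 and 1.40 times, against 0.838 to 1.24 times. The ratio of 3′ to 5′ signal of Gapdh, a sign of RNA integrity, was 5.29, 3.48 and 2.63 in the mesonephros-derived replicates and 1.94 to 2.86 in the ovary-derived ones. That of Actb did not rise with it, at 0.887, 0.93 and 0.894 against 0.92 to 1.01.

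**Figure D1:**
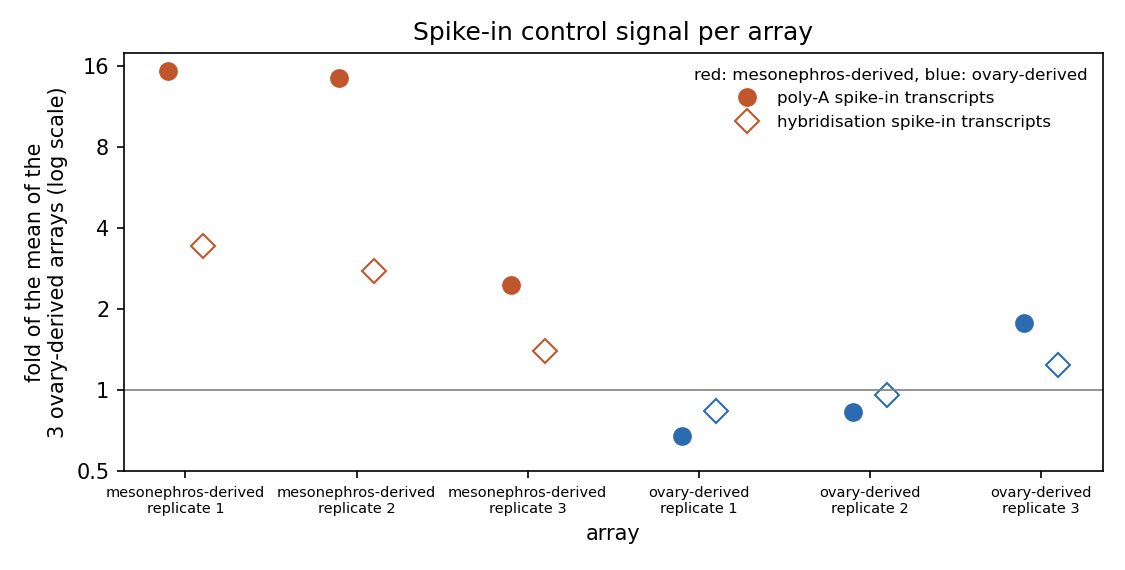
Signal of 2 kinds of spike-in control transcripts on each of the 6 arrays, as a fold of the mean of the 3 ovary-derived arrays on a log scale; filled circles are poly-A spikes added before amplification and open diamonds are spikes added at hybridisation. Poly-A spikes read 15.3-fold and 14.46-fold in mesonephros-derived replicates 1 and 2, and 2.46-fold or less on the other 4 arrays.

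Of 11703 genes tested, 4 were higher and 1 was lower in mesonephros-derived cells at an adjusted p of 0.05 (limma). Myh11, the smooth muscle myosin heavy chain, had a signal of 11880 ± 964 against 3158 ± 504 in ovary-derived cells (mean ± SD, n = 3 each), 3.77-fold higher (log2 change 1.92 ± 0.18 SE, limma adjusted p = 0.0277). Tagln, an actin-binding protein of smooth muscle, was 2.78-fold higher (1.48 ± 0.16 SE, adjusted p = 0.0341). Dpep1, a membrane dipeptidase, was 8.25-fold higher (3.04 ± 0.34 SE, adjusted p = 0.0341), with a signal of 5657 ± 2277 against 637 ± 130 (SD, n = 3). Adamts5, a secreted protease that cleaves proteoglycans, was 7.04-fold higher (2.82 ± 0.34 SE, adjusted p = 0.0457), and its mean over all of its probe sets was 1.35 and did not pass (adjusted p = 0.243). Kctd14 was 5.18-fold lower (−2.37 ± 0.29 SE, adjusted p = 0.0493), at 660 ± 238 against 3377 ± 637 (SD, n = 3).

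The next genes in order of p, picked only among those without overlap between the groups, did not pass the threshold. On the higher side were Actg2, the gamma smooth muscle actin, at 1.58 ± 0.21 log2 units (SE), Acta2, the alpha smooth muscle actin, at 1.23 ± 0.19, Mylk, the myosin light chain kinase, at 1.20 ± 0.18, Tpm2, a tropomyosin, at 1.14 ± 0.16, Myom1, a myomesin, at 1.66 ± 0.24, and Rbpms, an RNA-binding protein, at 1.25 ± 0.18. Their adjusted p-values in limma lay between 0.064 and 0.0865. On the lower side, Slc26a7, an anion transporter, had a signal of 102 ± 31.9 against 1037 ± 356 (SD, n = 3; limma adjusted p = 0.0514), with the mesonephros-derived mean close to the floor. Il1b, the cytokine interleukin 1 beta, was at least 3.28-fold lower and Pianp at least 3.96-fold lower, since all 3 mesonephros-derived arrays lay below the floor. Aplnr, the apelin receptor, had a log2 change of −1.99 ± 0.31 (SE) and Hsd11b2, which inactivates glucocorticoids, one of −1.93 ± 0.34. Hs3st3a1, a heparan sulfate sulfotransferase, stood at −1.99 ± 0.35, Scml4 at −1.72 ± 0.28 (−0.18 as the mean of its probe sets), Wdr77 at −1.62 ± 0.26 and the transcription factor Cebpd at −1.46 ± 0.25, and adjusted p-values for the genes from Il1b on lay between 0.0861 and 0.106.

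At an unadjusted p of 0.05, 756 genes were higher and 845 lower, and the groups did not overlap for 22.2% of the genes tested. Chance gives 10% for arrays of equal noise. The SD around the group means was 0.58 to 0.82 log2 units on mesonephros-derived and 0.25 to 0.315 on ovary-derived arrays, so 10% is no firm reference here. The number of calls rested on single arrays: it was 46 without mesonephros-derived replicate 1, 3 without replicate 2, and 0 without mesonephros-derived replicate 3 or any one of the ovary-derived arrays, with 638 to 2432 genes at an unadjusted p of 0.05 in these fits. With arrays weighted by their noise limma called 129 genes, 87 higher and 42 lower, and with eBayes fitted without the intensity trend, with a plain test or with the poly-A spike signal as a covariate it called 0, with 1504, 1317 and 305 genes at an unadjusted p of 0.05.

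**Figure D2:**
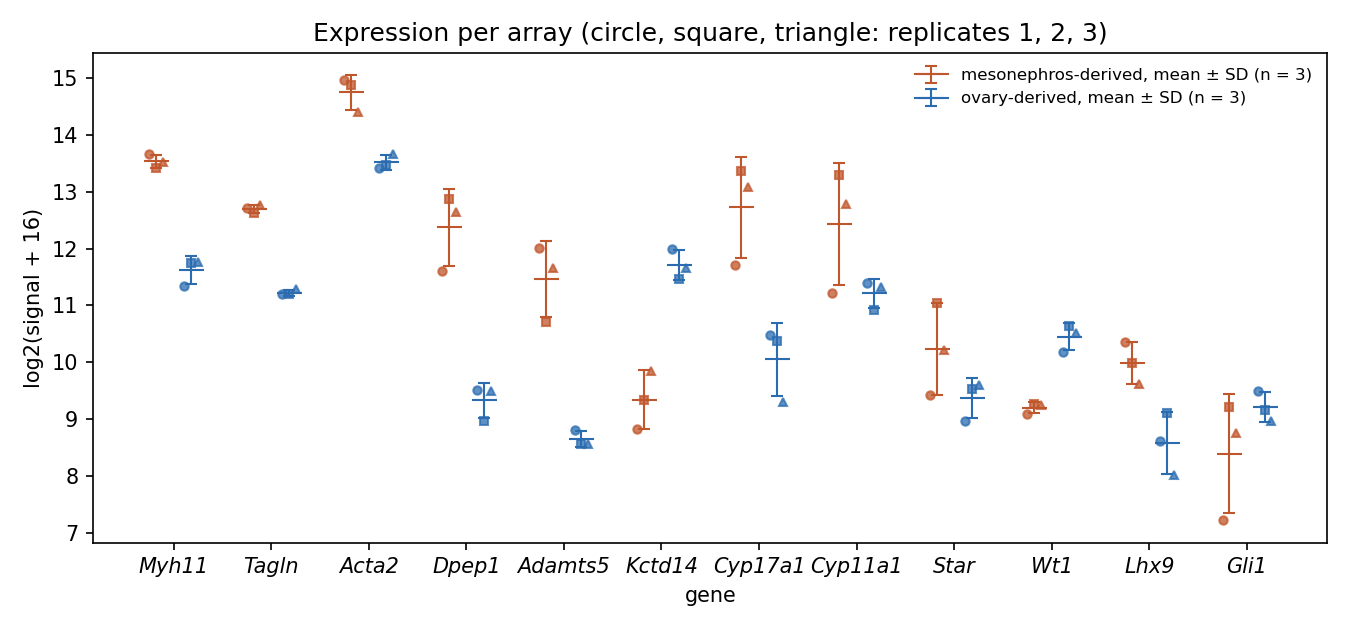
Expression of 12 named genes on each array, on the y axis as log2(signal + 16); circles, squares and triangles are replicates 1, 2 and 3, and bars are the mean ± SD of 3 arrays. Myh11, Tagln, Dpep1, Adamts5 and Kctd14 passed the threshold, while Cyp11a1, Star and Gli1 overlapped between the groups.

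The smooth muscle and pericyte list was higher by camera (adjusted p = 2e-13) and with fry (0.0232), and was not past the threshold with an estimated correlation (adjusted p = 0.132). All 17 of its members were higher in mesonephros-derived cells, 11 of them past the threshold when adjusted over the list alone and 2 (Myh11 and Tagln) when adjusted over all genes. The median log2 change was 0.87. The list mean stood at 0.63, 1.11 and 0.95 log2 units above the ovary-derived mean in mesonephros-derived replicates 1, 2 and 3, with an SD of 0.06 between the ovary-derived arrays. The 11 contractile members had a median of 1.05 and the 6 pericyte members one of 0.28.

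The androgen synthesis list, which covers the steroid output of theca cells, was also higher by camera (adjusted p = 0.0237) but not with an estimated correlation (adjusted p = 0.367). Of its 10 tested members 7 were higher, 2 past the threshold when adjusted over the list alone and 0 when adjusted over all genes. Cyp17a1, which makes androgens from progestogens, had a signal of 7537 ± 3751 against 1112 ± 431 (SD, n = 3), a log2 change of 2.67 ± 0.46 (SE), with a limma adjusted p of 0.00239 over the list alone and 0.106 over all genes. Fdx1, the ferredoxin that feeds electrons to mitochondrial steroid enzymes, stood at 0.96 ± 0.22 (adjusted p = 0.00977 over the list alone). Cyp11a1, which cleaves the cholesterol side chain, stood at 1.22 ± 0.46, Star, which brings cholesterol into mitochondria, at 0.86 ± 0.40 and Hsd3b1 at 0.39 ± 0.24, and all 3 overlapped between the groups. Without mesonephros-derived replicate 2 Cyp11a1 fell to 0.79 and Star to 0.46, and Hsd3b1 fell to 0.21 without ovary-derived replicate 2. Hsd3b1 fell on the other side of 0 after quantile normalization. Nr5a1, the nuclear receptor that drives steroidogenic genes, stood at −0.43 ± 0.32, or −0.09 without mesonephros-derived replicate 2, with another probe set at 0.09. The list mean stood at 0.28, 0.46 and 0.64 log2 units in mesonephros-derived replicates 1, 2 and 3, with an SD of 0.10 between the ovary-derived arrays. By camera the list did not pass after quantile normalization (0.107), without mesonephros-derived replicate 3 (0.177) or without ovary-derived replicate 2 (0.0716). It passed with array weights (0.000355) and with the poly-A spike signal as a covariate (0.014). The cholesterol synthesis and uptake list did not pass by camera (adjusted p = 0.216), with 15 of 20 members lower, Dhcr7 at −0.90 ± 0.29 among them.

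The hedgehog pathway was examined because the label was driven by Gli1. Gli1 itself had a signal of 376 ± 225 in mesonephros-derived and 583 ± 110 in ovary-derived cells (SD, n = 3), with a log2 change of −0.81 ± 0.50 (SE, limma adjusted p = 0.484) and one of −0.23 without mesonephros-derived replicate 1. Adult Gli1 does not test the labels, since the cells were marked months before collection, and the reporter transcript was not analysed here. Ptch1, the hedgehog receptor and target, stood at −0.08 ± 0.23, with its other probe sets from −1.39 to −0.53. Hhip, another target, stood at −0.43 ± 0.29, with its other probe sets from −1.21 to −0.73, at −0.14 without mesonephros-derived replicate 2 and at 0.20 with the poly-A spike signal as a covariate. Of 13 tested members 10 were lower and 0 passed the threshold adjusted over the list alone. Sufu, an inhibitor of the pathway, had the smallest p at −0.91 ± 0.27, with another of its probe sets on the other side of 0. The co-receptors Cdon and Boc stood at −0.97 ± 0.41 and 0.72 ± 0.43, with Cdon at −0.64 without mesonephros-derived replicate 2 and Boc at 0.22 without replicate 1. Another probe set of Boc stood at −0.09. The target Foxf1 stood at −1.23 ± 0.58, or −0.58 without mesonephros-derived replicate 1. Camera gave an adjusted p of 0.193.

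Transcription factors of the gonad and mesonephros moved in both directions, and the list as a whole did not pass (camera adjusted p = 0.863). Its median log2 change was 0.16 and its mean −0.04. Of 12 tested members, 1 was higher and 1 lower when adjusted over the list alone. Wt1, a regulator of the gonad and kidney primordia, was lower at 574 ± 37.2 against 1395 ± 222 (SD, n = 3; log2 change −1.25 ± 0.24 SE, limma adjusted p = 0.0064 over the list alone and 0.149 over all genes). Lhx9, a regulator of the early gonadal ridge, was higher at 1.41 ± 0.35 (adjusted p = 0.0182 over the list alone and 0.229 over all genes), with other probe sets from 0.50 to 0.86. Emx2, needed for the urogenital system, stood at −1.43 ± 0.48, the estrogen receptor Esr1 at −0.63 ± 0.31, Gata4 at −0.34 ± 0.22, Tcf21 at 0.36 ± 0.21 and Nr2f2 at 0.33 ± 0.15, the last on the other side of 0 after quantile normalization. Esr1 stood at −0.35 without mesonephros-derived replicate 3, Gata4 at −0.16 without replicate 1 and Tcf21 at 0.23 without ovary-derived replicate 3. Among theca growth factors and receptors, 9 of 23 members were higher and 14 lower, with a camera adjusted p of 0.628. The growth factor receptor Igf1r was lower at −1.23 ± 0.28 (adjusted p = 0.0419 over the list alone and 0.207 over all genes), while Bmp7 at −1.17 ± 0.38, Bmp2 at −0.88 ± 0.32 and Tgfbr3 at 0.43 ± 0.17 did not pass. Pdgfra, a receptor of stromal cells, stood at −0.02 ± 0.17, with other probe sets from −0.70 to 0.22.

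Matrix genes were higher by camera (adjusted p = 3.43e-06) but not with an estimated correlation (adjusted p = 0.297). Of 30 tested members 23 were higher, 6 of them past the threshold when adjusted over the list alone and 0 when adjusted over all genes. Col1a1, the main chain of collagen I, stood at 1.00 ± 0.23 log2 units (SE), Sparc at 0.77 ± 0.18, Thbs2 at 0.77 ± 0.20 and Col4a1, a basement membrane collagen, at 0.66 ± 0.18. Sparc and Thbs2 each had another probe set on the other side of 0. The list mean was 0.48, 0.29 and 0.25 in replicates 1, 2 and 3, and the list did not pass after quantile normalization (0.0721) or with the poly-A spike signal as a covariate (0.149). Cytosolic ribosomal protein genes were also higher by camera (adjusted p = 3.42e-13) but not with an estimated correlation (adjusted p = 0.612), with 34 of 39 members higher and 20 past the threshold when adjusted over the list alone, such as Rps29 at 1.04 ± 0.25 and Rpl35 at 0.72 ± 0.19. Their mean stood at 0.71, 0.39 and 0.12 log2 units in mesonephros-derived replicates 1, 2 and 3, where poly-A spikes read 15.3, 14.46 and 2.46 times the ovary-derived mean. The list turned to the other direction after quantile normalization (adjusted p = 0.263), with a median of −0.06, and with the spike covariate (0.868). Oxidative phosphorylation genes did not pass (adjusted p = 0.0862), with 43 of 74 members higher before quantile normalization and a median of 0.06 that turned to −0.13 after it. They passed as higher with array weights (0.00243), without ovary-derived replicate 1 (0.00763), without mesonephros-derived replicate 2 (0.0275) and over all probe sets (0.0467).

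**Figure D3:**
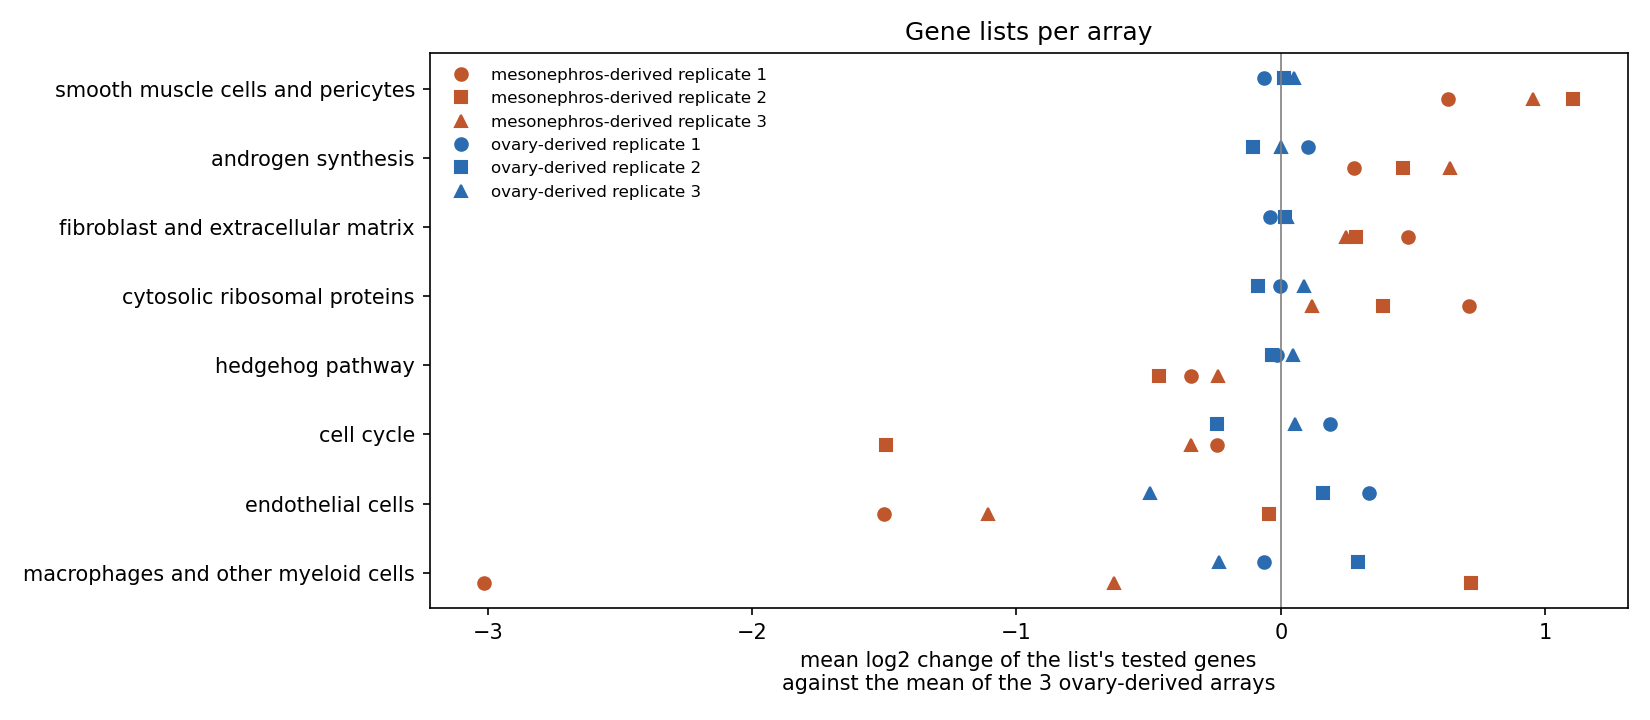
Mean log2 change of the tested genes of 8 gene lists on each of the 6 arrays, on the x axis against the mean of the 3 ovary-derived arrays; red symbols are mesonephros-derived and blue symbols ovary-derived arrays, and circles, squares and triangles are replicates 1, 2 and 3. Smooth muscle genes lie 0.63 to 1.11 above the ovary-derived mean on all 3 mesonephros-derived arrays, while macrophage genes lie at −3.02, 0.72 and −0.63.

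Cell cycle genes were lower by camera (adjusted p = 4.24e-05) but not with an estimated correlation (adjusted p = 0.612), with 24 of 25 members lower and 0 past the threshold when adjusted over the list alone. The replication factor Mcm3 stood at −1.59 ± 0.42 log2 units (SE), Mcm4 at −1.04 ± 0.31, Pcna at −0.83 ± 0.28 (−0.50 without mesonephros-derived replicate 2) and the mitotic kinase Aurka at −1.37 ± 0.47, and the mean of Aurka's probe sets lay on the other side of 0. The list mean was −0.24, −1.49 and −0.34 in replicates 1, 2 and 3, and the list did not pass with the spike covariate (0.178). The interferon response list did not pass (adjusted p = 0.0862), with 12 of 15 members lower, among them Bst2 at −0.76 ± 0.20 and Ifit2 at −1.12 ± 0.36. It passed without mesonephros-derived replicate 2 (0.0109), without ovary-derived replicate 1 (0.022) and with no floor (0.0487). The dissociation and immediate early response list did not pass (adjusted p = 0.375), with 16 of 24 members lower. Its mean was 0.77, −0.56 and −0.79 in replicates 1, 2 and 3. By camera it passed as lower without mesonephros-derived replicate 1 (5.68e-07), with the spike covariate (3.84e-18), array weights (4.23e-05) or quantile normalization (0.0179). It turned to higher without replicate 2 (0.867) or replicate 3 (0.426). These camera values assume a correlation of 0.01 between genes, while the estimate for this list was 0.787. Camera with that estimate gave an adjusted p of 0.868 in the main setting. Ier2 was lower at −1.47 ± 0.27 (limma adjusted p = 0.126 over all genes) and passed over the list alone, and the heat shock gene Hspa1a stood at 1.59 ± 0.51, overlapped between the groups and turned to −0.39 with the spike covariate, and it stood at 1.03 without mesonephros-derived replicate 1.

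Markers of other ovarian cell types were followed in the sorted cells. Endothelial markers were lower by camera (adjusted p = 0.00575) but not with an estimated correlation (adjusted p = 0.612), with 11 of 14 members lower, 2 past the threshold when adjusted over the list alone. These were Sox18, a transcription factor of vessels, at −1.52 ± 0.39 log2 units (SE), and Robo4, a vascular guidance receptor, at least 2.42-fold lower. Kdr at −2.89 ± 0.93 (−1.85 without mesonephros-derived replicate 1) and Pecam1 at −1.97 ± 0.72 overlapped between the groups. The list mean was −1.50, −0.05 and −1.11 in mesonephros-derived replicates 1, 2 and 3, and the adjusted p was 0.0932 without replicate 1 and 0.129 without replicate 3. Macrophage markers were lower by camera (adjusted p = 0.0237) but not with an estimated correlation (adjusted p = 0.666), with 16 of 16 members lower and 0 past the threshold when adjusted over the list alone. Csf1r, the receptor macrophages need, stood at −2.88 ± 1.12, or −1.26 without mesonephros-derived replicate 1, with other probe sets from −1.75 to −0.03, and Mrc1 at −1.71 ± 0.46, while Cd52 was at least 1.5-fold lower. The list mean was −3.02, 0.72 and −0.63 in replicates 1, 2 and 3, and without replicate 1 the list turned to the other direction (adjusted p = 0.871). It did not pass without mesonephros-derived replicate 3 (0.128), without ovary-derived replicate 2 (0.104), with the floor at the 60th percentile (0.205) or with the spike covariate (0.318).

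Granulosa markers did not pass (camera adjusted p = 0.863), with 3 of 7 tested members higher, and Foxl2, a granulosa and stromal transcription factor, stood at −0.18 ± 0.20 log2 units (SE), or −0.07 without mesonephros-derived replicate 1 and −0.05 without ovary-derived replicate 2, with another probe set at 0.14. Luteal markers did not pass as a list (adjusted p = 0.42), with Rgcc lower at −1.71 ± 0.37 (limma adjusted p = 0.00694 over the list alone) and Sfrp4 higher at 1.56 ± 0.39 (0.00798 over the list alone). Below the floor in their mean over the 6 arrays, and not tested, were 6 of 13 granulosa and 2 of 7 luteal markers. Among these, mean signals were 259.6 in mesonephros-derived against 27.8 in ovary-derived cells for Amh and 32.7 against 174.7 for Nr5a2. The luteal markers Akr1c18 and Ptgfr had 169.9 against 12.3 and 152.3 against 62.7. The others lay below the floor in both group means. Adipocyte markers did not pass (adjusted p = 0.178), with 3 of 4 tested members higher. Fabp4, a fatty acid carrier, was at least 2.66-fold higher against an ovary-derived group below the floor, with mesonephros-derived replicate 1 below it too. Its log2 change was 2.26, or 3.23 without mesonephros-derived replicate 1 and 1.61 without replicate 2. The adipocyte list passed without mesonephros-derived replicate 1 (0.00164), with array weights (0.00351) and with the spike covariate (0.014). Tubule epithelial markers had 3 tested members of 11 on the array and did not pass (adjusted p = 0.863). Of 15 oocyte markers 14 lay below the floor in their mean over the 6 arrays and were not tested, as were all 13 lymphoid and all 12 ovarian surface epithelial markers. Some rose above it in a group or on an array, such as Nobox with an ovary-derived mean signal of 143.5, Cd8a with a mesonephros-derived one of 138.9, and Krt19 with 162.4 on its highest array. Erythroid markers had 1 tested member, at −0.55, or 0.46 without mesonephros-derived replicate 2.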

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

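Of the tests in this part, the spike covariate on the smooth muscle list, the random lists and quantile normalization were chosen after the result was seen. The control probe sets, which take part in no comparison, were above the highest ovary-derived array (1.78 for poly-A and 1.24 for hybridisation spikes) on all 3 mesonephros-derived arrays. The poly-A spikes read 15.3, 14.46 and 2.46 times the ovary-derived mean in replicates 1, 2 and 3, and the hybridisation spikes 3.42, 2.77 and 1.40 times. A candidate explanation is a lower mass of sample RNA on these arrays, most of all replicates 1 and 2; the amount of RNA was not analysed here, and what it predicts for the gene lists is tested next (the ribosomal list stood at 0.12 in replicate 3).

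The smooth muscle and pericyte list was 0.90 log2 units higher in mesonephros-derived cells on average. With the poly-A spike signal as a covariate the difference was 0.95 ± 0.31 (SE). That fit separates spikes from the group only weakly, since every mesonephros-derived array read above every ovary-derived array, and it cannot decide on low input. In replicate 3, whose spikes were nearest to the ovary-derived arrays, the difference was 0.95. On that 1 array, this value argues against low input as the whole cause. After quantile normalization its median was 0.75, against 0.87 before, and 0 of 10000 random lists matched on brightness had a median as high, which argues against a shift of bright probe sets. A larger share of contractile smooth muscle cells stays open: 21 of 22 tested genes of a second smooth muscle list, written before their values were seen, were higher, with a median of 0.61, and the same values could come from more contractile transcript per cell. A larger share of pericytes cannot be told apart from an equal one, since the pericyte median of 0.28 lay between the values that would decide it; the origin of the cells, which the design names, stays open as untested.

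Several other lists differed unevenly between the mesonephros-derived arrays. The ribosomal protein list stood at 0.71 and 0.39 in replicates 1 and 2 but at 0.12 in replicate 3, which lay 1.4 SD of the ovary-derived arrays from 0, and its median turned to −0.063 after quantile normalization. Both low input and a shift of bright probe sets may account for it, since the brightest 5% of genes had a median of 0.28 against −0.11 in the dimmest of 5 brightness bins. Low input could not be decided for the macrophage list (−0.63 in replicate 3, with replicates 1 and 2 at −3.02 and 0.72), the endothelial list (−1.11, with −1.50 and −0.05) or the cell cycle list (−0.34, with −0.24 and −1.49). Replicates 1 and 2 had nearly equal spike signals, and a varying share of other cell types in each sort stays open as untested.

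The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real split mixes both groups on each side. Such a split keeps part of any group difference and puts the rest into the spread, so it is no reference free of that difference. The counts below therefore do not decide whether a list's change came by chance. The real split called 5 genes and the highest of the other splits 0, so that 1 of 10 gave as many. For the lists, the real split called 7 and the highest of the others 6, so that 1 of 10 gave as many. Splits other than the real one took the smooth muscle list past the threshold in 5 of 9 cases with a lowest adjusted p of 4.41e-05, against 2e-13, the matrix list in 5 (0.00146 against 3.43e-06) and the androgen synthesis list in 0 (0.0642 against 0.0237). For the other called lists, a split other than the real one gave a lower adjusted p. These were the cell cycle list (1.11e-10 against 4.24e-05, past the threshold in 7), the macrophage list (1.69e-10 against 0.0237, in 6), the endothelial list (2.94e-10 against 0.00575, in 3) and the ribosomal list (2.02e-13 against 3.42e-13, in 5). Some lists not called in the real split passed in others. The immediate early list did so in 6 (lowest camera adjusted p of 9.19e-20), the interferon and adipocyte lists in 3 each, and the oxidative phosphorylation list in 1.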

How the results depend on the processing

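Comparisons with replicate 3 alone and with the spike covariate were chosen after seeing the data; the rest were fixed before. The cause was not tested for any change given here. The number of genes called was 5 (4 higher, 1 lower) and became 3 (0 lower) with a pseudocount of 1, 2 (2 higher, 0 lower) after median centring, 8 (2 lower) with the mean of probe sets, 3 (0 lower) over all probe sets, 129 (87 higher, 42 lower) with array weights, and 0 with eBayes without trend, a plain test or the spike covariate, at 1504, 1317 and 305 genes with an unadjusted p under 0.05. The lower call became 2 with the floor at the 60th percentile and 0 with robust fitting. Replicate 3 alone against the ovary-derived arrays, which assumes that it varies like them, gave 350 (181 higher, 169 lower), among them all 5. Leaving out 1 array gave 0 to 46 genes, 0 to 32 higher and 0 to 14 lower. Same-numbered arrays deviated from their group means with correlations of −0.000479, 0.0711 and −0.01, which show no pairing by number. With 3 arrays per group these values cannot exclude one. With the replicate block 4 genes passed, 3 higher and 1 lower, 4 of them among the 5.

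Of 18 lists 7 passed by camera, 0 with an estimated correlation, 1 with fry and 4 to 9 on leaving out 1 array. After quantile normalization 5 passed, 4 of them among the 7, and with the spike covariate 5, of them 3 among the 7, without the matrix (0.149), ribosomal (0.868), cell cycle (0.178) and macrophage (0.318) lists. For the androgen synthesis list the adjusted p of 0.0237 became 0.107 after quantile normalization, 0.0633 without _x_at and _s_at probe sets, 0.0541 without trend, 0.367 with an estimated correlation, 0.132 with fry and 0.00687 to 0.177 on leaving out 1 array. The smooth muscle list passed in every setting except an estimated correlation (0.132), and the hedgehog list, at 0.193, passed in none.

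Direction turned for the ribosomal list after quantile normalization (0.263) and with the spike covariate (0.868), and for the oxidative phosphorylation list after quantile normalization (0.263). The macrophage list turned on leaving out 1 array (1.41e-06 to 0.871). Lists that passed in few settings or none also turned. The transcription factor list did so with no floor (0.647), quantile normalization (0.59), the mean of probe sets (0.818), array weights (0.703), replicate 3 alone (0.276), the spike covariate (0.149), fry (0.689) and leaving out 1 array (0.528 to 0.968). The immediate early list turned over all probe sets (0.948) and on leaving out 1 array (5.68e-07 to 0.923), and the granulosa list with replicate 3 alone (0.918) and on leaving out 1 array (0.871 to 0.968). The luteal list turned with replicate 3 alone (0.874) and the spike covariate (0.553). The tubule epithelial list turned over all probe sets (0.948), with array weights (0.987), replicate 3 alone (0.793), the spike covariate (0.382), fry (0.928) and leaving out 1 array (0.772 to 0.968).

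Among named genes, with log2 changes, quantile normalization turned Hsd3b1 (−0.16) and Nr2f2 (−0.12), and the spike covariate turned Hsd3b1 (−0.27), Boc (−0.37), Hhip (0.20), Hspa1a (−0.39), Hoxb6 (−0.43) and Pdgfra (0.17). The mean of probe sets turned Sparc (−0.077) and Aurka (0.054). Pdgfra also turned after median centring (0.057), with array weights (0.064) and with replicate 3 alone (0.12). On leaving out 1 array, with the probe set of each gene chosen anew, Boc ranged from −0.31 to 0.99 (0.22 at the lowest on the main probe set), Ptch1 from −0.34 to 0.079 and Pdgfra from −0.089 to 0.10. Over the named genes, 1548 of the values kept direction and side of the threshold. A further 80 passed only in the alternative and 49 only in the main setting. Only the 5 genes called in the main setting could lose a call, so all 49 fell on them, over 22 settings. Most of the 1548 came from genes past the threshold in neither setting, so this number does not show stable calls. Dim signals limit the folds of genes near the floor.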

Other observations

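Hox genes, which keep a record of position along the body axis, had no list of their own and were looked at after their values had been seen. Only Hoxa10 and Hoxa11 were in a list, that of transcription factors, and neither was among the genes tested. Of the tests on the Hox genes, the permutation, the spike covariate and quantile normalization were chosen after the result was seen, and the one on replicate 3 before. In mesonephros-derived cells 13 of 14 tested genes of clusters A, B and C were higher, with a mean log2 change of 0.77, and 4 of 5 tested genes of cluster D were lower, with a mean of −0.50. Hoxb3 stood at 1.22 ± 0.44 (SE), Hoxb6 at 1.23 ± 0.49 (−0.43 with the spike covariate), Hoxc6 at 1.21 ± 0.47 and Hoxc8 at 0.56 ± 0.22, against −1.57 ± 0.31 for Hoxd10 and −0.87 ± 0.30 for Hoxd9. Hoxb9 in the first set and Hoxd11 in cluster D went the other way. Of these 19 genes 0 passed the threshold in limma over all genes tested; at an unadjusted p of 0.05 they were the 6 named with values here.

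The difference between the 2 sets was 1.26 log2 units, and it was 1.03, 1.53 and 1.22 in mesonephros-derived replicates 1, 2 and 3 with an SD of 0.13 between ovary-derived arrays. The value of 1.22 in replicate 3 cannot decide on low input, because the grouping by cluster was chosen from changes that include this array. With the poly-A spike signal as a covariate the difference was 1.32 ± 0.35 (SE), in a fit that separates spikes from the group only weakly. Quantile normalization left the difference at 1.34. A two-sided exact permutation of the cluster labels over all 11628 assignments gave p = 0.00189, but the grouping was chosen from the same values and genes of 1 cluster are not independent, so random order among the Hox genes stays open. Different cell types in the 2 sorts, and the origin of the cells, which the design names, stay open as untested.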
